A study of Mus musculus with 4 samples.

How the data were processed

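The data were 4 single-cell RNA-seq libraries (10x 3' chemistry) of mouse pancreas, 1 per group. Per the labels, all mice were C57BL/6 and had received saline or caerulein, which causes pancreatitis, followed by 12 weeks of recovery. The pancreata were taken either without mutant Kras (mtS after saline, mtC after caerulein) or 2 days after activation of KrasG12D (mktS after saline, mktC after caerulein). Per the labels, cells negative for the dead-cell stain DAPI and DAPI-negative cells positive for tdTomato were sorted separately and combined in about equal numbers in 1 tube per pancreas. Every share of cells below is therefore a share of a sorted mix and not of the tissue. The labels do not name the driver that recombines the reporter, and none is assumed here.

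The deposited values are raw UMI counts per gene and cell barcode, 1 matrix per library, as the authors made them with Cell Ranger. The submitters' processing notes name Cell Ranger 6.0.2 and the genome build mm10, whereas the file headers name Cell Ranger 5.0.0, and this was not resolved. The barcode and feature files held names only. Each matrix had 32287 features, including the reporter (tdToma) and a second feature, tdToma_minus, whose meaning no label gives and which was left out of every measure. Gene coordinates came from the GENCODE vM21 annotation of GRCm38.

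The matrices held 9744 (mtS), 11046 (mtC), 10417 (mktS) and 12372 (mktC) barcodes with medians of 1915.5, 1701, 3174 and 2348 UMIs. Cells with at least 500 UMIs, at least 200 genes and at most 20% mitochondrial UMIs were kept. Scrublet, run through scanpy with an expected doublet rate of 8%, marked 1.27%, 2.78%, 0.0114% and 2.01% of cells under its automatic threshold. Where that threshold marked under 0.5%, as in mktS, the top 8% of scores were removed instead. This left 5365, 6404, 8075 and 9295 cells with medians of 3395, 2494, 4040 and 3251 UMIs. The gene minimum removed 3732, 3783, 1070 and 1638 barcodes, the mitochondrial limit 578, 676, 568 and 1248, and the doublet step 69, 183, 704 and 191.

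Cells of all libraries were clustered together without batch correction. Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes and 30 principal components were used, and a graph of 15 neighbours was clustered with the Leiden method at resolution 1. The 33 clusters were named from marker genes of 21 cell classes, fixed beforehand. Each took the class with the highest mean log2 fold over the mean of the other clusters, if at least 3 of its markers were detected. The 6 clusters whose detected markers, leading genes, UMI counts or library make-up did not meet the naming rules stayed unnamed. A class name with "-like" means expression of its markers and nothing more. The work used Python 3.11.15, scanpy 1.11.5, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, leidenalg 0.10.2, python-igraph 0.11.9, scikit-image 0.26.0 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 for TMM factors.

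UMIs were summed per gene over the acinar-like cells of each library and divided by all UMIs of those cells, and the result was scaled to 1000000 (CPM). With 1 library per group, the 4 pairwise comparisons and the difference between the genotypes leave no spread between libraries to test against, so these are values without p-values. An additive model of history and genotype would leave 1 residual degree of freedom, but it takes the caerulein ratio as equal in both genotypes and was not fitted. Values carry exact 95% Poisson intervals (CPM and ratios) or exact binomial intervals (shares), which cover counting error only and leave out differences between mice. Intervals of the difference between the caerulein ratios of the genotypes cover counting error only too, but are normal approximations from the UMI counts, not exact. The 4 comparisons were caerulein-recovered against saline without and with mutant Kras, and mutant Kras against none after saline and after caerulein. A gene was counted as at least 2-fold apart when its ratio was 2-fold or more, with 10 CPM in the higher library, 20 UMIs over both libraries, and a 95% interval of the ratio wholly on 1 side of no difference. Zero counts were handled with a floor of 3 counts, so such ratios and shares are printed as limits. Limits of shares and CPM at 0 counts lie below the upper bounds of the exact 95% intervals. For gastric-type genes in epithelial cells of mtS, for example, the limit was 0.120% and the exact bound 0.148%. The genes named in the text for each comparison are the 10 higher and 10 lower genes with the largest log2 ratio by the bound of its interval nearest 0, up to 4 members per gene list ranked the same way, and Kras. Mitochondrial, ribosomal protein, haemoglobin, immunoglobulin and sex-linked genes, unnamed transcripts and genes below the free RNA limit were left out of the ranking of 10. Further members of lists are named as examples.

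Of 29 gene lists fixed before the data were examined, each was summarised as the median log2 ratio of its members with a pseudocount of 1 CPM and at least 2 CPM on average. It was set against 10000 random lists matched for expression, and a list beyond percentiles 2.5 or 97.5 of these is called outside the random range. Members at least 1.5-fold apart were counted as higher or lower. A gene was called past the free RNA limit when its CPM in acinar-like cells of the higher library was at least a 10th of its highest CPM in any other named class of that library. Since unnamed clusters are left out of this limit, it was also computed with each unnamed cluster of at least 10 cells counted as a source. Shares of cells with a UMI of a gene were taken after each cell had been thinned to 1000 UMIs, with shallower cells left out.

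The counting rule was tested on simulated data: Poisson counts were drawn for both libraries of each comparison from their pooled profile at their own depths, with 200 genes changed 4-fold or 2.5-fold. All 4-fold changes were recovered. Recovery of 2.5-fold changes was 98% (higher) and 100% (lower) for caerulein without Kras, 94% and 96% for caerulein with Kras, 98% and 90% for Kras after saline, and 98% and 96% for Kras after caerulein. Of the unchanged genes 0, 0, 0 and 1 were called, of 1174, 1588, 1115 and 1464. The simulation held counting error only, so it cannot show how the rule behaves under free RNA or differences between cells, clusters or mice.

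The comparisons, lists and rules were fixed before the data were examined, and so were these alternatives: scaling by UMIs outside the digestive enzyme list or by TMM, equal weight per cell, thinning to 1000 UMIs, doublets kept, a mitochondrial limit of 10% or none, 1000 UMIs per cell, Leiden resolutions of 0.5 and 2, variable genes without enzyme, immediate-early and ribosomal genes, only clusters without a library over 90%, 1.5-fold, other CPM minima, other pseudocounts and list minima, and thinning to 500 and 2000 UMIs. A further 6 alternatives were added after the data had been seen: no gene minimum per cell, acinar-like cluster 3 alone, list members past the free RNA limit only, the same with unnamed clusters counted, unnamed macrophage clusters added to that class, and clustering without metaplasia and enzyme genes. Apart from cluster 21, added to macrophage-like cells in 1 of these, cells of unnamed clusters entered no class comparison. The unnamed gastric-type cluster was counted with acinar-like and ductal-like cells only for the share of cells with gastric-type genes. Genes of the trypsin, amylase and Reg families have close paralogs, so their reads may be shared between family members.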

Results

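Pancreas cells were compared between mice that had recovered for 12 weeks from caerulein pancreatitis and mice given saline, without mutant Kras and 2 days after activation of KrasG12D. Kras, the gene targeted in mktS and mktC, had 3.93 CPM (2.99 to 5.06) in acinar-like cells of mtS, 4.37 (3.36 to 5.59) of mtC, 2.28 (1.14 to 4.08) of mktS and 5.64 (3.83 to 8.01) of mktC, and 42.0, 38.6, 41.3 and 34.4 CPM in ductal-like cells. The 3' reads cannot tell the mutant from the normal allele, so these values check nothing about the activation. The tdTomato reporter was read at 238, 255, 272 and 280.0 CPM in acinar-like cells. Each group had 1 library, so every difference below is between these libraries, and intervals cover counting error only. Xist, the X-inactivation RNA, had 0.158 CPM over all kept cells of mtS, 0 UMIs in mtC, 654 CPM in mktS and 799.6 CPM in mktC, and the Y-linked Ddx3y had 40.7, 28.6, 0 and 0 CPM, so every comparison of mutant Kras with none also compares these sex-linked patterns. Genotype may also coincide with a library or sequencing batch, which 1 library per group cannot separate. The gene minimum removed 3732 of 9744 barcodes of mtS and 3783 of 11046 of mtC, against 1070 of 10417 of mktS and 1638 of 12372 of mktC.

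Within the sorted mix, acinar-like cells made up 28.8% (27.6 to 30.1) of mtS, 27.8% (26.7 to 28.9) of mtC, 5.87% (5.37 to 6.40) of mktS and 9.21% (8.63 to 9.82) of mktC. T-like cells, which carried Cd3d, Cd8a and Lef1, were 27.3% (26.2 to 28.4) of mtC and 0.522%, 0.272% and 0.377% of mtS, mktS and mktC. B-like cells were also most frequent in mtC, at 5.73% against 0.280% in mtS. Macrophage-like cells were 7.18%, 4.03%, 14.0% and 24.5% in the same order of mtS, mtC, mktS and mktC. The unnamed cluster 21, whose nearest class was macrophage, held a further 0.0186%, 0.187%, 23.9% and 0.301%. With it these cells numbered 3058 of 8075 in mktS and 2307 of 9295 in mktC, so the share was then larger in mktS. Fibroblast-like cells were 13.2%, 3.58%, 13.1% and 20.2%, endothelial-like cells 12.1%, 2.56%, 4.72% and 3.27%, and ductal-like cells 18.5%, 10.2%, 4.84% and 15.1%. Mesothelial-like cells were 0.466% of mtS, 2.03% of mktS, 0.118% of mktC and 0 of 6404 cells of mtC, which allows a share of up to 0.0468%. The nearest class of the unnamed clusters 31 and 32 was also mesothelial, with 3 and 6 of its markers detected. Together they held a further 0.0559% of mtS, 18.0% of mktS, 0.0108% of mktC and 0 cells of mtC. These shares reflect about equal numbers of unselected and tdTomato-sorted cells, and 10.2%, 4.95%, 43.7% and 17.1% of the kept cells lay in unnamed clusters.

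**Figure D1:**
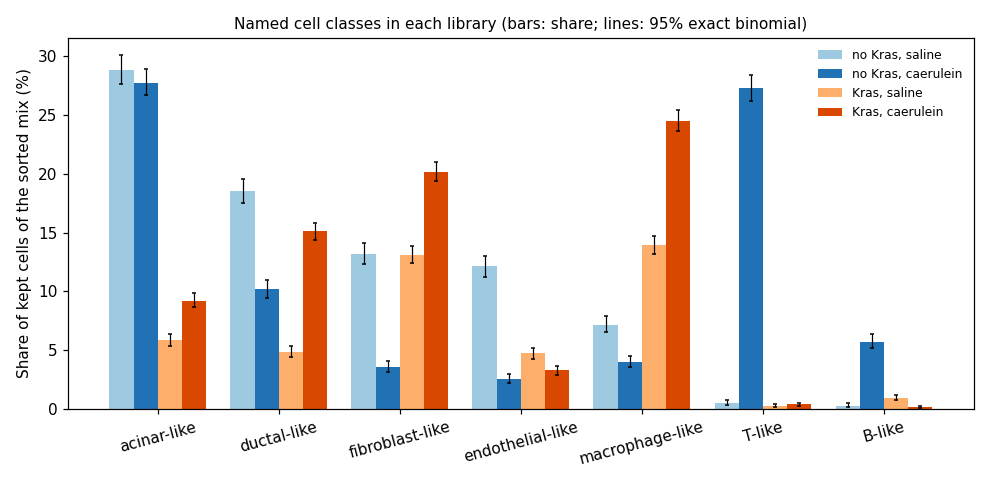
Share of kept cells (%) in 7 cell classes per library, with exact binomial 95% intervals. T-like cells made up 27.3% of the caerulein-recovered library without mutant Kras. Unnamed clusters are not shown, among them cluster 21, nearest to the macrophage class, with 23.9% of mktS.

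Acinar-like cells lay in clusters 3, 7 and 9, with 575, 750 and 222 cells of mtS, 1137, 525 and 116 of mtC, 367, 67 and 40 of mktS, and 581, 67 and 208 of mktC. Cluster 9, led by Rbpjl, Sel1l and Fam13a, had a median of 1279 UMIs per cell, against 5435 in cluster 3 and 4619 in cluster 7. Ratios over all acinar-like cells therefore also carry this make-up, and values in cluster 3 alone are given where they were much nearer 0.

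Without mutant Kras, acinar-like cells of the caerulein-recovered library had higher Reg3a (79.3 CPM in mtS, 516 in mtC; log2 ratio 2.70, 2.61 to 2.79), Reg3b (349 and 1991; 2.51, 2.47 to 2.55) and Reg3g (11.7 and 67.7; 2.53, 2.30 to 2.77), which encode secreted antimicrobial lectins of the inflamed pancreas. Reg2, of the same family, was at 5411 and 13398 CPM (1.31), and Reg3d at 259 and 450.4 (0.80), while Reg1 was nearly level (-0.01). Agr2, a disulfide isomerase of mucous cells, had 13 UMIs in mtS and 175 in mtC (0.865 and 12.1 CPM; 3.81, 2.999 to 4.75). Genes of other kinds on the higher side were Fetub (2.22), a liver-type protease inhibitor, the complement gene C4b (2.11), the ubiquitin fusion gene Uba52 (1.30), the Golgi glycosyltransferase Mgat2 (1.21) and the lysosomal protease Ctsl (1.05). The genes lowest in mtC were the nuclear long RNA Neat1 (-0.69, but -0.05, -0.24 to 0.13, in cluster 3 alone and 0.14 with at least 1000 UMIs per cell), the secretory cargo receptor Tmed11 (-0.65), the neuropeptide gene Gal (-0.65), Smim38 (-0.65), the trypsinogen Try10 (-0.57), Lars2 (-0.47), the metallothionein Mt2 (-0.41), and the proteases and granule proteins Ctrl (-0.39), Sycn (-0.35) and Cela1 (-0.32).

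Of 25 measured genes of the unfolded protein and integrated stress response 15 were higher in mtC and 0 lower (median log2 0.66, above 100% of random lists, whose median was 0.29, with the call kept in 18 of 18 settings), among them the chaperones Hspa5 (0.90), Hyou1 (1.11), Canx (0.86) and Dnajb11 (0.82). Of 19 acinar transcription factors and secretory regulators 5 were higher and 0 lower, namely Cckar (0.83), the receptor for the hormone that caerulein mimics, Bhlha15 (0.79), Ptf1a (0.72), Gata4 and Creb3l1, with a list median of 0.35 inside the random range. In cluster 3 alone Cckar was at 0.44, Ptf1a at 0.42 and Bhlha15 at 0.34 (-0.10 to 0.79), all under 1.5-fold. Of 31 digestive enzyme genes 0 were higher and 0 lower, and their median of -0.13 lay below all random lists. Ribosome biogenesis genes had 7 of 17 members higher, such as Ncl, Fbl and Nop56 (0.48, percentile 99.7), but the 4 past the free RNA limit had a median of 0.20 at percentile 23.5. MHC class I genes had 4 of 8 higher, such as B2m, Tapbp and Psmb8 (0.52, percentile 99.4), with 1 past the free RNA limit. Mitochondrially encoded genes had 3 of 11 higher (0.52, percentile 99.5), with mt-Nd4l at 0.91 and mt-Nd5 at 0.76, but the list lay below its random median in 4 of 18 settings and inside the range in another 4. MHC class II genes had 3 of 5 higher (0.57, percentile 98.4), with 0 past the free RNA limit, and the list lay below its random median in 6 of 16 settings. Metaplasia and gastric-type genes had 3 of 9 higher, which were Gkn3, Agr2 and Pigr (0.48, percentile 98.1), but the 4 past the free RNA limit had a median of 0.38 at percentile 80.1, and the call was lost in 11 of 18 settings. The 19 pancreatitis acute-phase genes split into 7 higher and 2 lower (0.30, percentile 64.3), and the 8 of them past the free RNA limit had a median of 1.17. Marker genes of other cells were lower in mtC: haemoglobin genes 4 of 4 (-1.27, percentile 0), myofibroblast genes 4 of 7 (-0.68, percentile 0), resident macrophage genes 2 of 5 (-0.43, percentile 0.0300) and inflammatory fibroblast genes 1 of 7, with 1 higher (-0.22, percentile 0.0300). Of these 4 lists 0, 0, 0 and 1 members were past the free RNA limit.

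MAPK target genes (-0.10, percentile 0.960), NF-kB and chemokine genes (-0.16, percentile 0.0200) and NRF2 and glutathione genes (0.06, percentile 2.44), which include Mt1 (-0.32), lay below the random range without a member at least 1.5-fold lower. None of the MAPK or NF-kB members was past the free RNA limit, the MAPK list was at its random median with equal weight per cell, and the NRF2 call was lost in 8 of 18 settings. In all, 33 genes were at least 2-fold higher and 10 at least 2-fold lower in mtC among 1488 compared, and 15 and 1 of these were past the free RNA limit (14 and 0 with unnamed clusters counted as a source). Of the genes named above, Reg3g and Neat1 then fell just below it. The median of all compared genes was 0.29 above 0, so the ratios are best read against that value. With UMIs outside the enzyme list or TMM factors as the scale, the split was 17 higher to 13 lower. It turned round with equal weight per cell, to 33 higher and 101 lower, and after thinning to 1000 UMIs, to 74 and 306.

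With mutant Kras, the caerulein history went with higher Agr2 (2.48 CPM in mktS, 28.0 in mktC; log2 ratio 3.50, 2.65 to 4.48), against 5.46 CPM in macrophage-like and 959 CPM in the unnamed gastric-type cluster of mktC. Gkn3, a gastrokine of mucous neck cells, was at 4.76 and 31.5 CPM (2.73, 2.09 to 3.42), but macrophage-like and ductal-like cells of mktC held 28.9 and 43.2 CPM and the gastric-type cluster 6903 CPM, so its acinar-like level is background. Also higher in mktC were Malat1 (893 and 3008 CPM; 1.75), Ewsr1 (1.76), Nktr (1.36), Neat1 (1.24), the rDNA-derived AY036118 (1.19), AC149090.1 (2.12) and Fam13a (2.09). The acinar transcription factor Rbpjl was at 41.8 and 113 CPM (1.43, 1.20 to 1.67), and Mecom, another acinar regulator, at 1.47. Most of these differences were smaller in cluster 3 alone, with Malat1 at 0.66, Neat1 at 0.56, Rbpjl at 0.42, Nktr at 0.17 (-0.49 to 0.84), Mecom at 0.55 (-0.29 to 1.42) and AC149090.1 at 1.11 (-0.14 to 2.499), and with at least 1000 UMIs per cell Nktr was level. Reg3a (-0.00, -0.05 to 0.04), Reg3b (-0.13), Reg2 (-0.19) and Reg3d (0.08) were nearly level, and Reg3g was at 0.58. The stress-induced Nupr1 (0.68), the metallothioneins Mt1 (0.68) and Mt2 (0.88) and the lysosomal Ctsl (0.72) were higher. Lower in mktC were the elastase Cela2a (36381 and 22247 CPM; -0.71), the hormone gene Fgf21 (-1.13, but 1.33 after thinning to 1000 UMIs), Gucd1 (-0.95), the oxysterol hydroxylase Cyp39a1 (-0.92), the amylase Amy1 (-0.74), Pld3 (-0.74), Fxyd6 (-0.59), Herpud1 (-0.44), Cela1 (-0.32) and Tmed6 (-0.32).

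Of 11 mitochondrially encoded genes 10 were higher and 0 lower (median 1.05, above all random lists), such as mt-Nd2 (1.23) and mt-Atp6 (1.05), and all 11 were past the free RNA limit. Ductal and progenitor genes had 11 of 19 members higher and 0 lower (0.86, percentile 100), such as Krt19, Sox9 and Epcam, and MHC class II genes 5 of 5 (2.47, percentile 100). The ductal list was above the random range in macrophage-like cells of the same libraries too (0.60, with Krt8, Krt18 and Epcam higher), and H2-Aa was at 66.3 CPM in acinar-like and 5061 CPM in macrophage-like cells of mktC. Metaplasia and gastric-type genes had 6 of 9 higher, such as Tff1, Sox9 and Pigr (0.74, percentile 99.2), but with unnamed clusters counted as a source only 2 members, Tff2 and Dmbt1, were past the free RNA limit. The call of this list was lost in 4 of 17 settings, and at Leiden resolution 2 the list turned to -0.06 less its random median. AP-1 genes had 7 of 9 higher, including Jun, Junb and Atf3 (0.84, percentile 99.9), MAPK target genes 7 of 9, including Dusp5, Phlda1 and Hbegf (0.82, percentile 99.2), and the wider immediate-early list 15 of 28 (0.79, percentile 100). Of these 3 lists 0, 0 and 1 members were past the free RNA limit. At Leiden resolution 2 the lists less their random medians turned to -0.03, -0.13 and -0.19, and in cluster 3 alone the AP-1 and MAPK lists lay inside the random range. NRF2 and glutathione genes had 4 of 10 higher, namely Gclc, Txnrd1, Mt1 and Mt2 (0.62, percentile 98.1), a call that was kept in 7 of 18 settings. Digestive enzymes had 1 member higher, Prss1 (1.01, but -0.21 with at least 1000 UMIs per cell), 2 lower and 28 neither (-0.09, percentile 0), and glycolysis genes a median of -0.02 (percentile 0.395), with 0 members past the free RNA limit and the call lost in 5 of 16 settings. The unfolded protein response (0.34, percentile 88.7), with Hspa5 at 0.57 and Pdia6 at 0.63, the acinar transcription factors (0.19, percentile 12.6) and the acute-phase genes (0.37, percentile 88.5) stayed inside the random range. The 8 acute-phase genes past the free RNA limit, however, had a median of 0.04 at percentile 2.1, below that range. Myofibroblast genes had 1 of 7 members higher and 3 lower (-0.29, percentile 0), inflammatory fibroblast genes 2 lower, C3 and Saa3 (0.00, percentile 1.26), and haemoglobin genes lay below the range as well (-0.11, percentile 0.670). Less its random median, the inflammatory fibroblast list turned to 0.36 with no mitochondrial limit. The haemoglobin list turned to 0.02 with at least 1000 UMIs per cell. Sex-linked genes had 2 of 3 higher, Xist and Tsix (1.35, percentile 99.9).

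Between mktC and mktS 202 genes were at least 2-fold higher and 9 at least 2-fold lower among 1948 compared, 66 and 2 of them past the free RNA limit (55 and 2 with unnamed clusters counted, when Agr2, Gkn3, Malat1, AY036118, Ewsr1 and Nktr fell below it), and the median of all genes was 0.27. The split was 91 to 15 with UMIs outside the enzyme list as the scale and 58 to 31 with TMM, and at Leiden resolution 2 it turned round, to 95 higher and 149 lower. In acinar-like cluster 3, which held 367 of the 474 acinar-like cells of mktS and 581 of the 856 of mktC, Agr2 was at 3.87, and the split was 47 to 22. Cells with at least 1000 UMIs gave 30 higher and 24 lower genes.

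The difference between the 2 caerulein ratios, with mutant Kras less without, was -2.71 (-2.81 to -2.61) for Reg3a, -2.64 for Reg3b, -1.95 (-2.19 to -1.71) for Reg3g and -1.502 for Reg2. It was also negative for Fetub (-1.86), the glutathione transferase Gstp1 (-1.43), Uba52 (-1.31), Amy1 (-1.18) and Cela2a (-0.80). It was positive for Neat1 (1.93, 1.73 to 2.14), Rbpjl (1.63), Lars2 (1.41), Prss1 (1.33), Mt2 (1.29), Mt1 (1.00) and Nupr1 (0.58). Over the other settings it ranged from -2.63 to -0.85 for Fetub, -1.61 to 0.29 for Gstp1, -2.72 to -0.97 for Reg3g, 0.67 to 2.29 for Lars2 and 0.41 to 1.71 for Nupr1. It ranged from -0.10 to 2.36 for Neat1, 0.08 to 2.81 for Rbpjl and 0.05 to 1.90 for Prss1. For the other genes named here it kept its sign in these settings. The Gstp1 value of 0.29 (-1.27 to 1.84) came after thinning to 1000 UMIs. In cluster 3 alone it was -2.56 for Reg3a, -2.66 for Reg3b, -1.88 for Reg3g, 1.53 for Mt2 and 1.11 for Mt1, but 0.85 for Lars2, 0.61 (0.23 to 0.999) for Neat1 and 0.27 (-0.11 to 0.66) for Rbpjl. With at least 1000 UMIs per cell it was -0.10 (-0.55 to 0.34) for Neat1, 0.08 (-0.31 to 0.46) for Rbpjl, 0.05 (-0.59 to 0.68) for Prss1 and 0.67 for Lars2. Across 1488 genes the caerulein ratios of the 2 genotypes had a Pearson correlation of 0.146 and a Spearman correlation of 0.161, and 57.0% of genes lay on the same side of both medians. For the 726 genes past the free RNA limit in both the correlations were 0.294 and 0.305. The Kras ratios of the 2 histories, which share no library, had correlations of 0.657 and 0.334, and of 0.557 and 0.320 for 655 genes past the limit. None of these differences could be tested with 1 library per group.

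**Figure D2:**
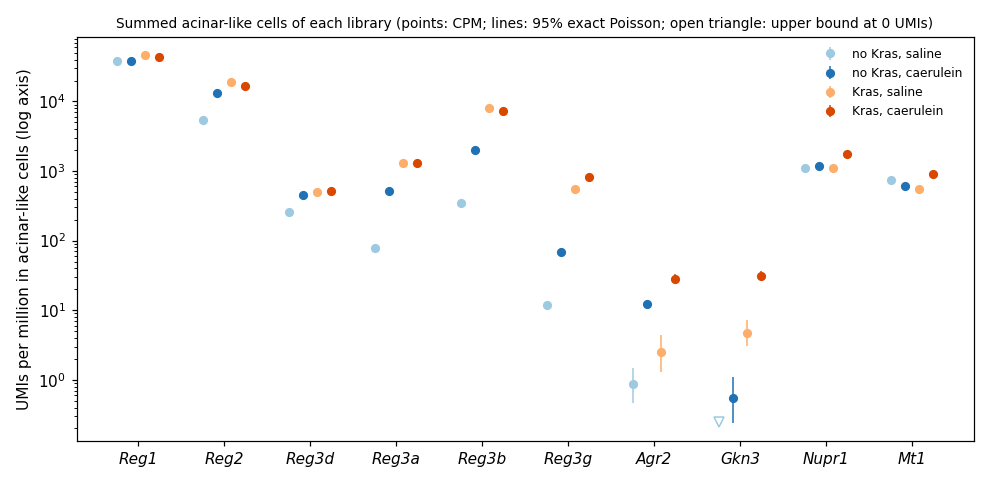
CPM (log axis) of 10 genes in acinar-like cells of each library, with exact Poisson 95% intervals. Open triangles mark upper bounds where no UMI was read. Reg3b was at 349 CPM in mtS and 8098 in mktS.

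After saline, 2 days of mutant Kras went with higher Reg3g (11.7 CPM in mtS, 550.2 in mktS; log2 ratio 5.55, 5.33 to 5.78), Reg3b (349 and 8098; 4.53, 4.49 to 4.58) and Reg3a (79.3 and 1323; 4.06, 3.97 to 4.15) in acinar-like cells. Reg2 (1.81) and Reg3d (0.94) were higher as well. The trypsinogens Prss1 (2.95) and Prss3 (1.12), whose paralogs share sequence, the complement gene C4b (2.05), Bex2 (1.57) and the snoRNA host Gas5 (1.00) were the other genes highest in mktS. Lower in mktS were Smim24 (-1.29), Zfp395 (-1.15), the elongation factor Tcea3 (-0.82), Neat1 (-0.77, but 0.23 with at least 1000 UMIs per cell), the chymotrypsin Ctrc (-0.71), the pancreatic lipase Pnlip (-0.69), Lars2 (-0.67), the phospholipase Pla2g1b (-0.61), Try10 (-0.47) and Cela1 (-0.46). The metallothioneins Mt2 (-0.48) and Mt1 (-0.43), Rbpjl (-0.45, but 0.22 with at least 1000 UMIs per cell), the water channel Aqp12 (-0.38) and the creatine synthesis gene Gamt (-0.37) were lower too, and Nupr1 was at -0.02.

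Of 19 acute-phase genes 15 were higher and 0 lower in mktS (median 1.81, above all random lists), such as Lcn2, Saa3 and Timp1 beside the Reg genes. The 8 past the free RNA limit had a median of 1.37, but with unnamed clusters counted only 6 Reg genes were past it (2.93). Saa3 and Timp1 were among the leading genes of the unnamed cluster 32 of mktS. Metaplasia and gastric-type genes had 5 of 9 higher (0.90, percentile 100), such as Agr2, Pigr and Msn, with Dmbt1 at 0.57 (0.10 in cluster 3 alone), and the 3 past the free RNA limit with unnamed clusters counted had a median of 0.57 at percentile 97.3, inside the random range. NF-kB and chemokine genes had 11 of 12 higher (1.98), MHC class I genes 6 of 8 (0.76), and actin and adhesion genes 13 of 19 (1.07), all above percentile 99. Cell cycle genes had 3 of 4 higher (1.02) and glycolysis genes 4 of 9 (0.53). Marker genes of other cells were higher in the same acinar-like cells: myofibroblast genes 7 of 7 (3.52), inflammatory fibroblast genes 6 of 7 (2.72), inflammatory macrophage genes 5 of 5 (2.72), haemoglobin genes 4 of 4 (4.33), lipid-associated macrophage genes 4 of 10 (0.41), resident macrophage genes 3 of 5 (0.79), MHC class II genes 3 of 5 (0.74) and interferon response genes 2 of 3 (0.80). None of the 12 NF-kB and chemokine genes was past the free RNA limit, and neither were any of the actin, cell cycle, glycolysis, MHC class II or interferon genes, while of the MHC class I genes 1 was. The MHC class II list lay below its random median in 5 of 16 settings, and the calls of lipid-associated macrophage and interferon genes were lost in 7 of 16 and 4 of 14. With no gene minimum per cell the haemoglobin list turned to -0.97 less its random median, 1 of 16 settings.

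Acinar transcription factors and secretory regulators had 0 members higher and 1 lower, Aqp8 (-0.04, percentile 0.600), and digestive enzymes 2 higher and 3 lower of 31 (-0.07, percentile 0). These 2 calls were lost in 4 and 3 of 18 settings. Mitochondrially encoded genes (-0.20, percentile 0.0400), with mt-Nd4l at -0.57 and mt-Nd5 at -0.31, AP-1 genes (-0.14, percentile 1.00) and immediate-early genes (0.03, percentile 1.06; 7 higher and 7 lower) lay below the random range. The immediate-early list moved above that range with at least 1000 UMIs per cell (0.25 less its random median, percentile 99.9) and at Leiden resolution 2 (0.34, percentile 99.9), the AP-1 call was lost in both settings, and mitochondrially encoded genes were at 0.06 with at least 1000 UMIs. None of the AP-1 or immediate-early genes was past the free RNA limit. MAPK target genes (0.25, percentile 64.5) and the unfolded protein response (0.07, percentile 6.42), with Hspa5 at 0.34 and Canx at 0.50 (0.09 and 0.08 in cluster 3 alone) and Fgf21 at -0.72, were inside it. In all, 91 genes were at least 2-fold higher and 14 at least 2-fold lower among 1458, with 16 and 3 past the free RNA limit (15 and 2 with unnamed clusters counted) and a median of 0.18. Of the genes named above, Gas5, Neat1 and Canx fell below the limit with unnamed clusters counted. The split was 67 to 27 with UMIs outside the enzyme list as the scale and 65 to 30 with TMM.

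After caerulein, mutant Kras went with higher Prss1 (3.47 CPM in mtC, 67.0 in mktC; log2 ratio 4.27), Reg3g (67.7 and 824; 3.61, 3.51 to 3.71), the secreted glycoprotein gene Lrg1 (3.21), Reg3b (1991 and 7398; 1.89), Prss3 (1.85), AC149090.1 (1.85), the snoRNA host Zfas1 (1.70), Reg3a (516 and 1319; 1.35) and Malat1 (1.26). Gkn3 was at 0.555 and 31.5 CPM (5.83, 4.82 to 7.06), a level in mktC that macrophage-like cells shared (28.9 CPM). Agr2 was at 12.1 and 28.0 CPM (1.21), Mecom at 1.54, Rbpjl at 1.18, Mt2 at 0.81, Mt1 at 0.57 and Nupr1 at 0.57. Lower in mktC were the threonine dehydrogenase Tdh (11.03 and 0.728 CPM; -3.92), Fetub (-1.48), Fgf21 (-1.40), the methionine cycle gene Mat1a (-1.28, but 0.09 with equal weight per cell), the glutathione-degrading Chac1 (-1.27), Gstp1 (-1.23), Uba52 (-1.12), Cela2a (-0.99), Amy1 (-0.87) and Pla2g1b (-0.82). The integrated stress response factor Atf5 was at -0.78, Gatm at -0.54 and Aqp12 at -0.53, whereas Xbp1 was at 0.49.

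The unfolded protein and integrated stress response was below the random range in this comparison (-0.13, percentile 0.0100), with 1 member higher and 3 lower of 25, namely Atf5, Chac1 and Fgf21. Acinar transcription factors were as well (-0.14, percentile 0.0200), with Rbpjl and Mecom higher and Ptf1a and Bhlha15 lower, and so were digestive enzymes (-0.14, percentile 0.0600; 3 higher and 4 lower of 31), though in cluster 3 alone the enzyme list was at 0.06 above its random median. Acute-phase genes had 14 of 19 members higher (1.87, percentile 100; 0.57 for the 8 past the free RNA limit). Metaplasia and gastric-type genes had 6 of 9 higher (1.26), ductal genes 11 of 19 (0.80), MAPK target genes 7 of 9, such as Areg, Ccnd1 and Hbegf (1.40), NF-kB genes 12 of 12 (2.02), MHC class II genes 5 of 5 (2.59) and actin genes 14 of 19 (1.24), all at percentile 100. Past the free RNA limit with unnamed clusters counted were 2 of the metaplasia, 2 of the ductal, 0 of the MAPK, NF-kB and MHC class II and 1 of the actin genes. AP-1 genes (0.66), NRF2 genes (0.59), MHC class I genes (0.62), immediate-early genes (0.37) and mitochondrially encoded genes (0.30) were above the random range too, but these calls were kept in only 7 of 16, 10 of 18, 10 of 16, 6 of 16 and 9 of 18 settings. The AP-1 and immediate-early lists lay below their random medians with at least 1000 UMIs per cell (-0.18 and -0.16) and in cluster 3 alone (-0.24 and -0.36), and the mitochondrially encoded list in 5 settings. Markers of other cells were again higher: haemoglobin 5.31, myofibroblast 3.96, inflammatory macrophage 3.31, inflammatory fibroblast 3.14, resident macrophage 2.19, endothelial activation 1.35 and lipid-associated macrophage genes 0.84. Cytosolic ribosomal proteins and nuclear oxidative phosphorylation genes stayed inside the random range in all 4 comparisons.

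Of 1963 genes 235 were at least 2-fold higher and 19 at least 2-fold lower in mktC, 48 and 11 of them past the free RNA limit (38 and 11 with unnamed clusters counted, when Gkn3, Agr2 and Malat1 fell below it), with a median of 0.15. The split was 168 to 30 with UMIs outside the enzyme list as the scale and 122 to 62 with TMM. In cluster 3 alone Malat1 was at -0.47, Rbpjl at -0.14, Mecom at 0.25, AC149090.1 at 0.11, Xbp1 at 0.17 and Zfas1 at 0.91.

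**Figure D3:**
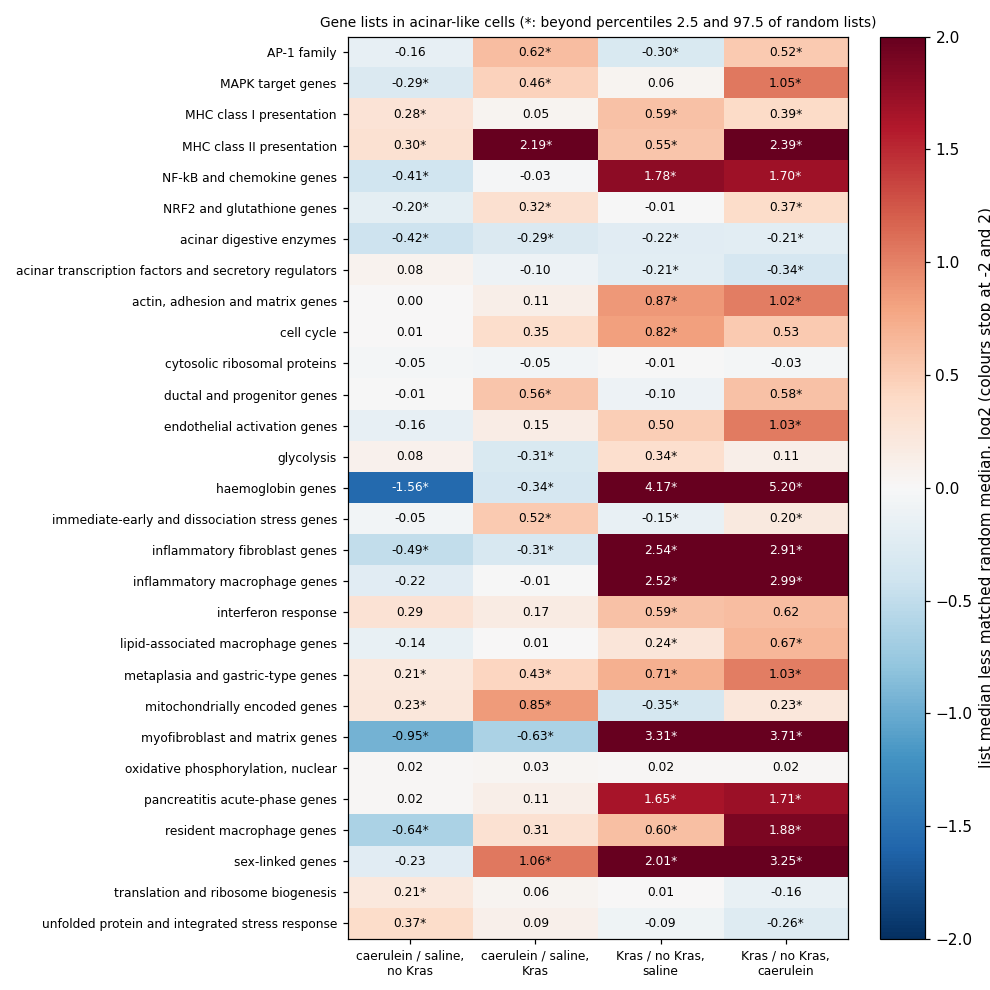
Median log2 ratio less the median of matched random lists for 29 gene lists (vertical) in the 4 comparisons (horizontal) in acinar-like cells. Asterisks mark lists beyond percentiles 2.5 or 97.5, and the unfolded protein response had 0.37 without mutant Kras.

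A group of cells with gastric-type genes was found almost only in mktC. Acinar-like cells, ductal-like cells and the cells of the unnamed gastric-type cluster are here called epithelial cells. After thinning to 1000 UMIs, 136 of 2411 epithelial cells of mktC (5.64%, 4.75 to 6.64) had at least 3 UMIs of 11 gastric-type genes. This compares with 1 of 852 in mktS (0.117%), 0 of 2490 in mtS, which allows up to 0.120%, and 0 of 2393 in mtC, which allows up to 0.125%. Of the 136 cells of mktC, 131 lay in the gastric-type cluster. Acinar-like cells of mktC had 1 of 727 (0.138%) and ductal-like cells 4 of 1372 (0.292%). Macrophage-like cells of mktC had 6 of 2259 (0.266%), and median depths before thinning were 3373 UMIs in acinar-like and 4174 in macrophage-like cells. The cells left out as too shallow numbered 60, 52, 27 and 166 among the epithelial cells of mtS, mtC, mktS and mktC. Clustered without metaplasia and enzyme genes, 317 of the 356 cells of the gastric-type cluster stayed together, in a cluster with 10, 17, 14 and 295 cells of mtS, mtC, mktS and mktC. In mktC the cluster had the foveolar peptides Tff1 (7719 CPM against 8.19 in acinar-like cells) and Gkn1 (6688 against 7.46), Gkn3 (6903 against 31.5), the neck mucin Muc6 (724), the surface mucin Muc5ac (207), pepsinogen C (Pgc, 841), Agr2 (959 against 28.0) and Tff2 (12500.3 against 3639). Krt19 was at 1293 CPM there and at 337 in ductal-like cells, and the acinar protease Cpa1 at 7433 against 28011 in acinar-like cells. These values pool all cells of the cluster in mktC, and only 131 of its 312 thinned cells had at least 3 UMIs of gastric-type genes. Its cells had digestive enzyme shares of 2.03% and 53.8% of UMIs at the lower and upper quartiles. The pooled values therefore do not show these genes together in the same cells. Of parietal and chief cell genes, Atp4b and Lipf had 0 UMIs, which allows up to 0.896 CPM, Atp4a had 16 (4.78 CPM, against 6.64 in ductal-like cells) and Cblif 18 (5.38 CPM, against 3.82 in acinar-like cells). The foregut factors Sox2 and Barx1 had 0 UMIs. The reporter was at 956 CPM (923 to 989.9) in this cluster, 280.0 in acinar-like, 148 in ductal-like and 101 in macrophage-like cells of mktC.

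**Figure D4:**
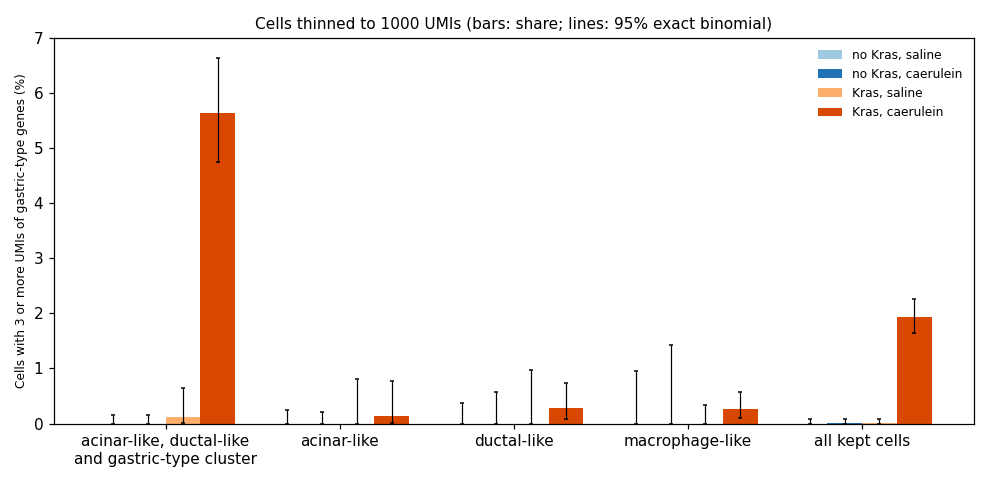
Share of cells (%) with at least 3 UMIs of gastric-type genes after thinning to 1000 UMIs, by cell class and library, with exact binomial 95% intervals. The share was 5.64% in epithelial cells of mktC.

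Single genes of ductal and mucous kind in acinar-like cells were also read after thinning. Krt8 was found in 9.15%, 7.04%, 7.22% and 13.3% of acinar-like cells of mtS, mtC, mktS and mktC and in 1.83%, 2.72%, 1.40% and 4.52% of macrophage-like cells. Before thinning the acinar-like shares of Krt8 were 29.0%, 28.4%, 28.1% and 39.3%. Agr2 was found in 0.134%, 1.499%, 0 of 457 cells (up to 0.656%) and 3.16% of acinar-like cells, with 0.664% of macrophage-like cells in mktC. Gkn3 was found in 5.36% of acinar-like and 3.41% of macrophage-like cells of mktC, and Pigr, the receptor that carries immunoglobulins across epithelia, in 5.64% and 1.20%. Clu was found in 31.8%, 40.0%, 31.5% and 45.9% of acinar-like cells and in 8.09%, 7.39%, 5.52% and 17.5% of macrophage-like cells. Median UMIs before thinning were 4596, 4613.5, 5479 and 3373 in acinar-like and 3003, 2634, 2908 and 4174 in macrophage-like cells, and 49, 44, 17 and 129 acinar-like cells were too shallow.

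Macrophage-like cells numbered 385, 258, 1127 and 2279 in mtS, mtC, mktS and mktC. The unnamed cluster 21, whose nearest class was macrophage, was left out, with 1, 12, 1931 and 28 cells. All 11 resident macrophage genes were lower in mtC than in mtS (median -1.62, below all random lists), and 10 of 11 were lower in mktC than in mktS (-1.77). With cluster 21 added, the list less its random median went from -1.71 to -0.70 (percentile 0.0100) between mktC and mktS, with Lyve1 at -1.04, Folr2 at -0.16 and Mrc1 at 0.69. It was -1.79 between mtC and mtS. Lyve1, the hyaluronan receptor, was at 275 CPM in mtS, 69.3 in mtC, 376 in mktS and 75.9 in mktC. The scavenger receptor Cd163 was at 443, 88.2, 294 and 61.6 CPM, the phosphatidylserine receptor Timd4 at 57.9, 3.78, 21.6 and 2.13, the folate receptor Folr2 at 427, 139, 350.4 and 147, and F13a1 at 1106, 364, 1189 and 441 CPM. Cluster 0, led by Lyve1, Cd163 and Folr2, held 63.6% of macrophage-like cells of mtS, 34.9% of mtC, 52.9% of mktS and 24.1% of mktC, whereas cluster 10, with Ccr2 and Cx3cr1, held 29.1%, 49.2%, 25.6% and 40.3%, and cluster 11, with Retnla and Ear2, held 23.3% of mktC. The monocyte receptor Ccr2 had a log2 ratio of 0.49 without and 1.47 with mutant Kras, and the interleukin gene Il1b 0.66 and 1.94. The antigen presentation genes H2-Ab1 (0.43 and 1.55), H2-Aa (0.22 and 1.26) and Cd74 (0.26 and 1.43) were under 1.5-fold apart without mutant Kras. With it they were higher, as were 7 of 7 MHC class II genes (1.48). MHC class I genes had 8 of 15 members higher in mtC (0.68), with H2-K1 at 0.68, and Stat1 of the interferon response list was at 1.86.

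**Figure D5:**
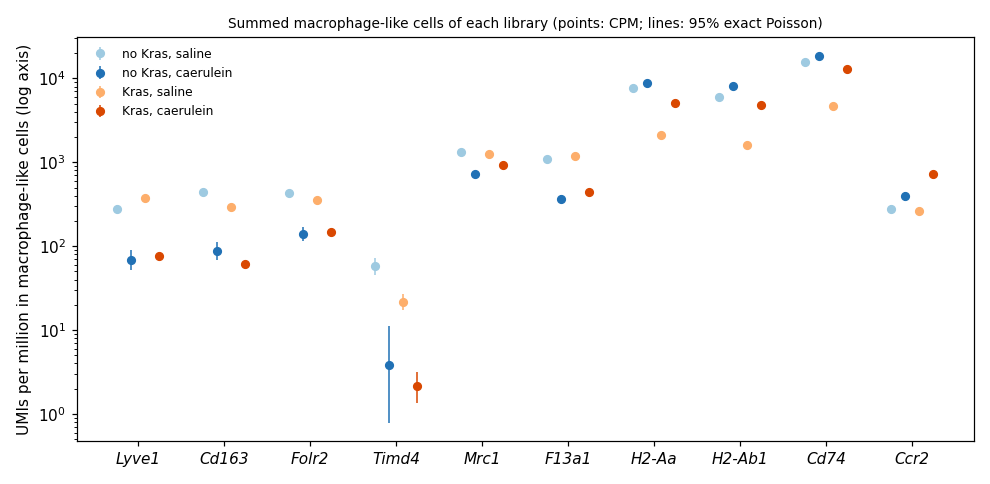
CPM (log axis) of 10 genes in macrophage-like cells of each library, with exact Poisson 95% intervals. Lyve1 was at 275 CPM in mtS and 69.3 in mtC.

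Against the saline library without it, macrophage-like cells of mktS had all 22 cell cycle genes higher (1.70), such as Mki67 (1.61). The cycling cluster 20, led by Mki67, Top2a and Birc5, held 3.38%, 10.1%, 20.6% and 12.3% of macrophage-like cells of mtS, mtC, mktS and mktC, so this ratio includes a change in the make-up of the class. With cluster 21 added, the cell cycle list less its random median went from 1.44 to 0.47. Also higher were 12 of 15 glycolysis genes (1.29), such as Ldha (1.66). All 7 MHC class II genes were lower there (-1.85), including H2-Aa (-1.85) and Cd74 (-1.71). The arginase gene Arg1 had 0 UMIs in mtS and 949 CPM in mktS, against 12.7 CPM in fibroblast-like and 30.5 CPM in endothelial-like cells of mktS. Arg1 also led the left-out cluster 21. The osteopontin gene Spp1 was at 81.7 and 325 CPM. Between mktC and mtC the interferon response had 14 of 29 members lower (-0.59), with Stat1 at -1.76. MHC class I genes had 11 of 15 lower (-0.91), and Il6 was at 3.09.

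In ductal-like cells of mtC against mtS, 6 of 6 MHC class II genes were higher (1.93, above all random lists), with H2-Ab1 at 2.43, Cd74 at 2.31 and H2-Aa at 1.87 (31.4 CPM in ductal-like and 8861 in macrophage-like cells of mtC), next to 9 of 26 interferon genes (0.53), such as Ifit1 (1.16) and Stat1 (0.64), and 10 of 20 NF-kB genes (0.50), such as Cxcl2 (1.96), Vcam1 (2.38) and Icam1 (0.75). The free RNA limit is defined for acinar-like cells only, so free RNA was not excluded for these genes in ductal-like cells. The Onecut family factor Onecut2 was higher after caerulein in both genotypes (1.94 and 1.53), as was Tm4sf1 (0.96 and 1.46). With mutant Kras, 9 of 18 metaplasia genes were higher in mktC than in mktS (0.59), such as Mmp7 (1.76), Foxq1 (1.32) and Dclk1 (1.21). Among genes of this list, Tff1 (7.84 and 10.5 CPM), Tff2, Gkn1 and Agr2 were no higher in ductal-like than in macrophage-like cells of mktC. Others were higher there, such as Gkn3 (43.2 and 28.9 CPM), Dclk1 (17.6 and 1.76) and Pigr (710 and 10.2). Free RNA was not excluded for this list in ductal-like cells, so its count and median may include it. Of 19 MAPK target genes in ductal-like cells, 3 were higher with mutant Kras after saline (median 0.32, percentile 99.8, random median 0.10) and 6 after caerulein (0.52, percentile 100, random median 0.09), with 0 lower in either. The ERK-induced factors Etv4 (1.31 and 2.66) and Etv5 (0.97 and 1.30) and the ERK phosphatase Dusp6 (0.82 and 0.58) were among these genes. Cell cycle genes had 20 of 22 members higher in both Kras comparisons (3.35 and 1.87), with Mki67 at 0.151 CPM in mtS, 4.49 in mtC, 69.5 in mktS and 65.5 in mktC. Ductal-like cells came mainly from clusters 12 and 16 in all libraries, and a cycling cluster, 17, held 0, 4, 23 and 66 of them.

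Fibroblast-like cells had higher myofibroblast and matrix genes with mutant Kras, 14 of 17 members after saline (1.71) and 15 of 17 after caerulein (1.85). The matrix genes Postn (4.73 and 3.91), Tnc (4.75 and 5.91) and Col1a1 (2.45 and 2.24) and the contractile Acta2 (4.39 and 4.98) were among them. Cluster 4, led by Col8a1, Tnc and Postn, held 1, 2, 112 and 370 of the fibroblast-like cells of mtS, mtC, mktS and mktC, so these ratios include a change in the make-up of the class. Acta2 (3.27), Tagln (3.12) and Col8a1 (2.87) were also higher in mktC than in mktS, and Saa3 (-3.39), Cxcl12 (-1.98) and C3 (-1.75) were lower. Saa3 and C3 were among the leading genes of the unnamed cluster 31, which had 1203 cells in mktS and 1 in mktC. Free RNA from it was not excluded for these 2 genes. AP-1 genes were lower with mutant Kras after saline (-0.96) and after caerulein (-0.75), with Fos at -1.26 and -1.005 and Jun at -1.01 and -1.02. The interferon response had 19 of 30 members higher in mktS than in mtS (1.05), and 18 of 30 lower in mktC than in mktS (-0.71), where Ifit1 was at -1.17 and Stat1 at -0.74. Most fibroblast-like cells of mtS, 472 of 708, lay in cluster 5, led by Smoc2 and Penk, whereas 832 of 1059 in mktS and 1486 of 1877 in mktC lay in cluster 2, led by Pi16 and Clec3b, and mtC had 121 cells in cluster 2 and 106 in cluster 5. Endothelial-like cells had 3 of 7 MHC class II genes higher in mtC than in mtS (1.19), endothelial activation genes at 0.45, with Selp at 0.69 and Cxcl10 at 1.03, and a cell cycle median of 2.42 in mktS against mtS. Free RNA was not excluded for the MHC class II genes of endothelial-like cells.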

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

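Of the tests below, that on free RNA for gastric-type genes, which used a clustering added later, and those on stomach tissue, prior pancreatitis, the gastric-type cluster as a source of Reg3 RNA, scaling, sex, and ductal and MHC class II genes in other classes were chosen only after the results had been seen. Those on free RNA for Reg3 genes among named classes and on doublets were set beforehand.

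Sex-linked genes, which entered the comparisons only as 1 of the 29 gene lists, split the libraries by genotype. Xist had 654 CPM over all kept cells of mktS and 799.6 CPM of mktC, and Ddx3y had 40.7 CPM in mtS and 28.6 CPM in mtC. The only Y-linked UMI in mktS or mktC among the 4 Y-linked genes examined was 1 of Kdm5d in mktS. Clusters that the naming rules left unnamed were a signal outside the main comparisons. Cluster 21, led by Arg1, Mmp12 and Chil3 and nearest to the macrophage class, held 23.9% of the kept cells of mktS. Clusters 31 and 32, led by Cxcl13, Saa3 and Serpinb2 and nearest to the mesothelial class, held 18.0% of mktS. Cluster 13, with low UMI counts and Cma1, Cpa3 and Mcpt4 in the lead, held 13.2% of mktC, and cluster 18, with gastric-type genes, held 3.42% of mktC.

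Caerulein ratios of acinar-like cells that lay on opposite sides in the 2 genotypes, below the random range without mutant Kras and above it with, or at least 1.5-fold lower and higher for genes, picked out MAPK target genes (0.75 in the list median less random median), NRF2 and glutathione genes (0.52) and Neat1 (1.93 in log2). Gaps of other lists, such as 1.88 for MHC class II genes, were larger, but these lists did not lie outside the random range on opposite sides. The difference was not tested for any of these, since each group had 1 library. All of these gaps depended on settings: Neat1 fell to 0.61 in cluster 3 alone and to -0.10 (-0.55 to 0.34) with at least 1000 UMIs per cell. The MAPK gap was 0.26 at Leiden resolution 2 and 0.71 in cluster 3 alone, and the NRF2 gap was 0.12 with equal weight per cell and 0.30 in cluster 3 alone.

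The gastric-type cells of mktC were weighed against technical explanations. Free RNA from other cells would leave no cluster once these genes were removed, but 41.2% of the cells of the cluster found without them had at least 3 UMIs of these genes, against 0.266% of macrophage-like cells. Stomach tissue without a recombined reporter would carry about as little tdTomato as macrophage-like cells (101 CPM), and the whole cluster had 956 CPM. Of its thinned cells in mktC, however, only 131 of 312 had at least 3 UMIs of gastric-type genes. In mtS, mtC and mktS 0 of 10, 0 of 14 and 1 of 14 of its cells had them, at 993, 1196 and 2458 CPM of tdTomato. The reporter of the gastric-type cells alone was not measured, so this test cannot decide. If they were doublets, most of these cells would be marked as such, provided that the marking caught most doublets, and 0.746% (1 of 134, 0.0189 to 4.09) were. Of all scored cells of mktC 2.01% were marked, against an expected rate of 8%, so many doublets may have gone unmarked. The cluster also had a median of 8835.5 UMIs in mktC, against 3251 in all kept cells. This test therefore cannot exclude doublets. Prior pancreatitis together with mutant Kras may have given rise to these cells, but with 1 library in this group that hypothesis cannot be told apart from a difference between mice.

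The higher Reg3a, Reg3b and Reg3g of both Kras libraries were weighed next. If free RNA had carried these genes, some other class would hold more UMIs per cell. In 6 of 6 gene and library pairs acinar-like cells held the most among named classes. Reg3b in mktS had 82.5 UMIs per acinar-like cell against 12.5 per T-like cell, and Reg3g 5.61 against 1.27. These values were not adjusted for depth, and the median depth in mktS was 5479 UMIs in acinar-like and 1327 in T-like cells. The 6 of 6 outcome may therefore partly reflect depth, and by itself it cannot exclude free RNA from shallower classes. The unnamed gastric-type cluster held more than acinar-like cells in 4 of the 6 pairs, such as 66.6 UMIs of Reg3b per cell in mktC against 47.5. Free RNA from the gastric-type cluster was taken to bring its Gkn3 along in the same ratio. The Gkn3 UMIs in acinar-like cells then allowed 0.875% of the UMIs of Reg3g in mktS to come from there. The upper bound was 1.85%, and the share was less for the other genes and library. Cells of the cluster without Gkn3 are not covered, and in mktC 131 of 312 thinned cells had at least 3 UMIs of gastric-type genes. In mktS the ratio rests on 14 cells with 88 Gkn3 UMIs. Scaling by a few abundant genes would bring the ratios to 0 under another scale, but the lowest log2 ratio over 3 scalings was 0.86. Sex of the mice could not be separated from genotype, as 0 libraries with mutant Kras had UMIs of Ddx3y.

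Ductal and MHC class II genes in acinar-like cells of mktC against mktS were weighed last. If free RNA carried the difference, the same lists would be shifted in other classes, a test that holds only where those classes do not make these genes. The ductal list was shifted by 0.73 in macrophage-like, 1.25 in endothelial-like and 1.41 in fibroblast-like cells, against 0.56 in acinar-like cells, in line with free RNA. The MHC class II list was shifted by 1.49 in endothelial-like, 1.60 in ductal-like and 2.98 in fibroblast-like cells, against 2.19 in acinar-like cells. Free RNA would give such shifts, but endothelial-like and ductal-like cells also had this list higher in mtC than in mtS. Expression of their own was not excluded, so this test cannot decide for the MHC class II list. Some expression within acinar-like cells may remain under these shifts of 0.73 and 1.49, and these data cannot measure it.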

How the results depend on the processing

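Of these alternatives, no gene minimum per cell, cluster 3 alone, members past the free RNA limit, the same with unnamed clusters counted, unnamed macrophage clusters added to that class, and clustering without metaplasia and enzyme genes were added after the data had been seen. The Reg3 and Agr2 ratios given next kept their direction in all alternatives run for them. Between mtC and mtS the range was 2.43 to 2.76 for Reg3a and 2.24 to 2.52 for Reg3b. It was 1.56 to 2.90 for Reg3g and 3.34 to 4.49 for Agr2. Between mktS and mtS it was 3.74 to 4.12 for Reg3a, 4.21 to 4.56 for Reg3b and 4.23 to 5.94 for Reg3g. Between mktC and mktS Agr2 ranged from 2.99 to 5.06 and Gkn3 from 2.02 to 4.39. Among list medians in acinar-like cells 1582 values kept their side of the random range, 119 were stronger, 149 weaker and 40 reversed. Among named gene ratios 1034 stayed within the main counting interval, 734 moved outside it and 8 of at least 1.5-fold reversed. Of ratios under 1.5-fold, Rbpjl for Kras after saline went from -0.45 to 0.22 with 1000 UMIs per cell, and with TMM Dmbt1 went from 0.47 to -0.0242 and Xbp1 from 0.49 to just below 0 for Kras after caerulein. Class shares stayed within their interval in 52 and moved in 48 cases. In macrophage-like cells 304 list medians stayed and 6 reversed, all with cluster 21 added. With a 50 CPM minimum the caerulein correlations went from 0.146 to 0.0557 (Pearson) and from 0.161 to 0.231 (Spearman), and the Kras correlations from 0.657 to 0.673 and from 0.334 to 0.269. The setting of clusters without a library over 90% removed no acinar-like cluster, and without the defining genes the gastric-type cluster had 3.17% of mktC. Depth limits genes below 10 CPM.

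The counts below are given for caerulein without Kras (main 43), caerulein with Kras (211), Kras after saline (105) and Kras after caerulein (254), where they moved by over 1.5 times. A 1.5-fold limit gave 283, 592, 274 and 554, no CPM minimum 504, 924, 678 and 1479, and a 50 CPM minimum 14, 38, 24 and 36, which follows from the limits themselves. Equal weight per cell gave 134 (33 higher, 101 lower), 893, 311 and 1484. Thinning to 1000 UMIs gave 380 (74 higher, 306 lower) for caerulein without Kras, 170 for Kras after saline and 568 for Kras after caerulein. For caerulein with Kras, enzyme-free scaling gave 106 and TMM 89. For caerulein with Kras and Kras after caerulein, 1000 UMIs per cell gave 54 and 120, Leiden resolution 0.5 gave 401 and 389, a mitochondrial limit of 10% gave 492 and 428, no such limit 1025 and 1014, variable genes without enzyme, immediate-early and ribosomal genes 454 and 457, and cluster 3 alone 69 and 133. For caerulein with Kras, resolution 2 gave 95 higher and 149 lower against 202 and 9, so that the balance turned round. Leiden resolution 2 gave 478 for Kras after saline and 401 for Kras after caerulein. No gene minimum gave 443 for caerulein with Kras, 179 for Kras after saline and 967 for Kras after caerulein. The share of gastric-type cells among epithelial cells of mktC was 4.42% after thinning to 500 UMIs and 6.75% to 2000. These depths also change the cells counted, as 0 and 487 were too shallow. For these and all other counts the cause was not tested.

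Reversed values follow as log2 ratios for genes and as list medians less random medians for lists, and for all of them the cause was not tested. With 1000 UMIs per cell, Neat1 was at 0.14 for caerulein without Kras and 0.23 for Kras after saline. In the same setting Nktr was at -0.00267 and Prss1 at -0.21 for caerulein with Kras. Immediate-early genes were there at -0.0345 for caerulein with Kras, 0.25 for Kras after saline and -0.16 for Kras after caerulein, AP-1 genes at -0.18 for Kras after caerulein, haemoglobin genes at 0.0167 for caerulein with Kras and mitochondrially encoded genes at 0.0559 for Kras after saline.

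MHC class II genes for caerulein without Kras were at -0.0668 with Leiden resolution 0.5, -0.12 with resolution 2, -0.00907 thinned, -0.11 with doublets kept, -0.0562 with a mitochondrial limit of 10% and -0.0128 with no gene minimum. For Kras after saline they were at -0.19 with resolution 0.5, -0.25 with doublets kept, -0.13 with equal weight, -0.22 with the limit of 10% and -1.37 with no gene minimum. Mitochondrially encoded genes for Kras after caerulein were at -0.0832 with resolution 0.5, -0.14 with resolution 2, -0.00816 with the limit of 10%, -0.45 with no gene minimum and -0.0420 without the listed variable genes. For caerulein without Kras they were at -0.0375 thinned, -0.0276 with equal weight, -0.0765 with no gene minimum and -0.18 with no mitochondrial limit.

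With resolution 2, immediate-early genes were at 0.34 for Kras after saline, and for caerulein with Kras they were at -0.19, AP-1 genes at -0.0332, MAPK target genes at -0.13 and metaplasia genes at -0.0590. In cluster 3 alone for Kras after caerulein, Malat1 was at -0.47, Rbpjl at -0.14, AP-1 genes at -0.24, immediate-early genes at -0.36 and digestive enzymes at 0.0649. With equal weight, Mat1a was at 0.0874 for Kras after caerulein, NRF2 genes at -0.0227 for caerulein with Kras and MAPK target genes at 0.00605 for caerulein without Kras. Thinned to 1000 UMIs, Fgf21 was at 1.33 for caerulein with Kras. Thinned lists in other classes for caerulein without Kras were resident macrophage genes at -0.78 in ductal-like cells, haemoglobin genes at 0.11 and inflammatory macrophage genes at -0.32 in endothelial-like cells, and cell cycle genes at 0.16 in fibroblast-like cells, and MAPK target genes for Kras after saline were at 0.00214 in endothelial-like cells. Among members past the free RNA limit, with or without unnamed clusters counted, translation genes were at -0.0934 for caerulein without Kras. With no gene minimum haemoglobin genes were at -0.97 for Kras after saline, and with no mitochondrial limit inflammatory fibroblast genes were at 0.36 for caerulein with Kras. With cluster 21 added to macrophage-like cells for caerulein with Kras, interferon genes were at 0.20, cell cycle genes at 0.44, actin genes at -0.0913, haemoglobin genes at 0.36 and lipid-associated macrophage genes at -0.29, and the last list was at -0.29 for Kras after caerulein too.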

Other observations

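Plasma-like, dendritic-like and neutrophil-like cells and cluster 19 were not part of the comparisons above. Plasma-like cells made up 1.96%, 5.62%, 5.73% and 1.65% of mtS, mtC, mktS and mktC, and 338 of the 463 in mktS lay in cluster 8, led by Ighm and Slpi with few UMIs per cell, whereas cluster 25, led by Ighg2b and Igha, held 359 of the 360 in mtC. Dendritic-like cells, with Ccl17, Ccl22 and Xcr1, made up 0.671%, 2.72%, 1.02% and 3.87% in the same order. Cluster 19 was led by Cxcr6, Il7r and Icos and held both Gata3 and Areg, of type 2 innate lymphoid cells, and Trdc, Tcrg-C1 and Il17a, of gamma-delta T cells, so it is given by number. It made up 2.03%, 2.56%, 0.619% and 2.35%, and NK-like cells 0.615%, 1.64%, 0.347% and 0.409%. Neutrophil-like cells, with S100a8 and S100a9, made up 0.112%, 0.281%, 1.61% and 0.484%, and endocrine-like cells, with Ins2, Gcg and Sst, 2.42%, 0.687%, 0.817% and 0.839%. These are again shares of the sorted mix of 1 library per group.

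A cluster of acinar kind with few UMIs, cluster 6, made up 6.88%, 2.62%, 0.0619% and 0.161% of the kept cells of mtS, mtC, mktS and mktC, and entered no comparison. Haemoglobin genes in ductal-like cells had list medians of 6.56 between mktS and mtS and of -3.97 between mktC and mktS. In the gastric-type cluster of mktC, digestive enzymes took up 9.17% of the UMIs of the median cell, with quartiles of 2.03% and 53.8%, against 69.6% in acinar-like and 4.13% in ductal-like cells. The same cluster had Clu at 14254 CPM, Pigr at 531, Onecut2 at 353, Dclk1 at 117 and Reg3b at 6329 CPM.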
